A study of Homo sapiens with 9 samples.

How the data were processed

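Chromatin immunoprecipitation with sequencing was done in LNCaP cells with antibodies against EZH2, H3K27ac and H3K27me3, in cells infected with an empty knockdown lentivirus (control) or with one against EZH2 (shEZH2). Per the labels, cells were fixed 2 to 3 days after infection with 1% paraformaldehyde and chromatin was sheared to 200 to 500 bp. Samples were grouped by their titles. Each of the 6 groups analysed held 1 library, and 3 further samples, 2 of tagged EZH2 and 1 with another EZH2 antibody, were not analysed here. Reads were aligned with BWA 0.6.1 to hg19 and peaks were called with HOMER 4.1, per the submitters' processing notes.

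The authors called peaks in each library by itself, without an input library, per the file headers. EZH2 peaks were windows of fixed size at a false discovery rate of 0.001, with at least 4-fold more tags than the surrounding 10 kb. For H3K27ac and H3K27me3 the settings differed between the groups, per the file headers. Control lists used small windows joined into regions at a false discovery rate of 0.001, and shEZH2 lists used windows of 1000 bp joined into regions at a Poisson probability of 0.001. This makes shEZH2 regions wider and lowers the tag density needed for a call. The deposited signal is the number of tags in a region scaled by the authors to 10000000 tags per library. The deposited score is the caller's peak score, is not scaled for depth, and was used only to rank or stratify peaks within a list. The deposited fold over the local background and the local p-value describe each EZH2 peak against its surroundings, and the fold is quoted for named peaks. The deposited clonal fold, a ratio of observed to expected tags per position, and the focus fraction, the share of tags on the expected side of a peak, were not used here.

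Overlap meant at least 1 shared bp. Shares of peaks are given with 95% exact binomial (Clopper-Pearson) intervals, differences of shares with Newcombe intervals, medians with order-statistic intervals, and ratios of peak numbers with exact binomial intervals for the split of their sum. All of these cover counting error over peaks, which are not replicates, and say nothing of the spread between cultures. No p-value was computed. Each overlap was set beside 100 random placements of the other list on the same chromosomes and 100 moves of the peaks by 10 to 100 kb. Signal ratios were log2 of shEZH2 over control tags per kb at regions called in both lists. For strong EZH2 peaks, the shift at equal rank was the log2 of 15 normalised tags over the control value at the rank that 15 tags had in shEZH2, with percentile intervals from 1000 bootstrap draws of the peaks. Peaks were compared at equal score with Mantel-Haenszel weights. Unplaced contigs, the mitochondrial genome and 2 Mb on either side of each chromosome's longest stretch without a listed region were treated as 1 class of repeat-rich sequence, located from the lists themselves. Repeats elsewhere may lie outside this class. The overlap code was tested on simulated lists placed like the 23060 control EZH2 peaks: a planted share of 31.4% was recovered as 31.6% and a planted difference of -10 points as -10.2 (SE 0.62), and overlap numbers at 1 bp matched bedtools 2.31.1. At 50% of the peak covered they differed by up to 7 peaks, since coverage by several regions was summed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

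The overlaps, their alternatives and the rule for named regions were chosen before the data were examined. That rule took the 10 EZH2 peaks of highest score with and without H3K27me3, the 10 regions of highest score called in only 1 group for each target, and the 10 highest and lowest log2 ratios of each histone mark among regions with at least 50 tags. The rule had been written for promoters, to be applied by coordinates if no annotation of the same build was at hand. As no hg19 annotation or sequence was used here, promoter shares, the 12 gene lists fixed in advance and sequence content were not computed, and signal ratios were taken at all shared regions instead of at promoters. The split of peaks into 4 classes, the comparisons within each score value and between H3K27ac alone and H3K27me3 alone, the moved peaks, pairs of like width, the repeat-rich class, strong peaks and their shift at equal rank, the choices of strong pairs, windows of 100 kb, deciles of tags and named regions away from gaps were added after the data were seen. The alternatives chosen in advance were an overlap of at least 50% of the peak, a distance of up to 1 kb, the upper 50% of each list by score, lists of equal length, means within quartiles of the score, H3K27me3 of both groups together, autosomes alone, another scaling of the tags and a minimum of 50 tags.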

Results

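LNCaP is an established human prostate cancer cell line. EZH2 is the catalytic subunit of Polycomb repressive complex 2 and places trimethylation on lysine 27 of histone H3 (H3K27me3), a mark of silenced chromatin. Acetylation of the same residue (H3K27ac) marks active promoters and enhancers. The series title names the question: whether EZH2 has roles as an activator that need neither Polycomb nor its methylation. Chromatin immunoprecipitation with sequencing was done for EZH2, H3K27ac and H3K27me3 in cells carrying the empty knockdown vector (control) and in cells with a short hairpin against EZH2 (shEZH2), with 1 library per group. The 6 deposited peak lists from these groups were analysed, and the other 3 samples of the series were not analysed here. The EZH2 libraries held 13331155 tags in control and 14514395 in shEZH2. The H3K27ac libraries held 17438009 and 22175405, and the H3K27me3 libraries 33289172 and 26241104, in the same order. Signal is given as normalised tags, which the authors scaled to 10000000 tags per library. With no replicates, no difference between control and shEZH2 could be set against a spread between libraries, and the 95% intervals below cover counting error over peaks only.

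Fewer EZH2 peaks were listed in the knockdown library. The control list held 23060 EZH2 peaks and the shEZH2 list 9493, which is 2.43-fold fewer, at thresholds of 6.75 and 6.89 normalised tags per window, or 36.9 and 45.6 per kb. The share of all tags that lay in listed EZH2 peaks was 3.62% in control and 1.74% in shEZH2. The peak windows were 183 bp in control and 151 bp in shEZH2, each set from that library's fragment length.

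The histone lists went the other way in extent. H3K27ac regions numbered 58134 in control and 59233 in shEZH2, but covered 47.2 Mb and 149 Mb. H3K27me3 regions numbered 86120 and 99251 and covered 38.6 Mb and 246 Mb. The median H3K27ac region was 428 bp wide in control and 1831 bp in shEZH2, and the median H3K27me3 region 212 bp and 1535 bp. The control lists of both marks were called with narrower windows than the shEZH2 lists, and the density needed for a call was 3.63-fold higher in control for H3K27ac and 2.73-fold higher for H3K27me3. Region numbers, widths and covered lengths of the histone marks were therefore not comparable between the groups.

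**Figure D1:**
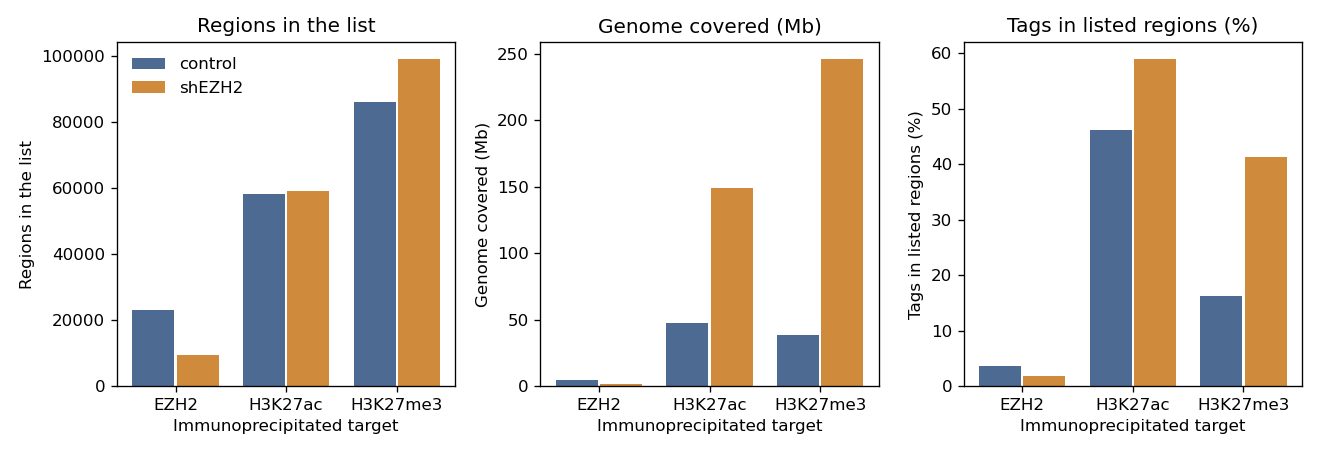
Number of regions, genome covered in Mb and percent of tags in listed regions for each target, with 1 bar per library (blue, control; orange, shEZH2). EZH2 peaks numbered 23060 in control and 9493 in shEZH2, while the H3K27me3 list, called with other settings in each group, covered 38.6 Mb and 246 Mb.

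The next comparison asked where EZH2 lay relative to its own mark and to active chromatin in control cells. EZH2 peaks formed a group on H3K27me3 and a group on H3K27ac, with few peaks on both. Of the 23060 control peaks, 9613 (41.7%, 95% exact binomial interval 41.0 to 42.3) overlapped H3K27me3 alone and 7348 (31.9%, 31.3 to 32.5) overlapped H3K27ac alone. A further 5517 (23.9%) overlapped neither mark and 582 (2.52%) both. Counting each mark by itself, 44.2% of peaks (43.6 to 44.9) lay in H3K27me3 and 34.4% (33.8 to 35.0) in H3K27ac. When the histone regions were placed at random on their chromosomes, these shares averaged 2.27% and 2.26% over 100 placements. When the EZH2 peaks were moved by 10 to 100 kb instead, they averaged 6.58% and 3.29%.

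H3K27ac was far more frequent at EZH2 peaks that lacked H3K27me3. Of 12865 EZH2 peaks without H3K27me3, 57.1% (56.3 to 58.0) overlapped H3K27ac, against 5.71% (5.27 to 6.18) of the 10195 with it. The difference was 51.4 percentage points (50.4 to 52.4). Few regions carried both marks: 2.08% of control H3K27ac regions touched an H3K27me3 region, against 4.07% at random placement and 2.29% after moves of 10 to 100 kb. EZH2 was frequent at the regions richest in each mark. An EZH2 peak lay in 49.2% (47.9 to 50.5) of H3K27ac regions in the highest decile of tags and in 1.70% of those in the lowest decile. For H3K27me3 regions these shares were 48.0% (47.0 to 49.1) and 1.75%. The highest deciles also held wider regions, with medians of 2373 bp for H3K27ac and 1483 bp for H3K27me3 against 151 bp in both lowest deciles.

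EZH2 peaks on H3K27me3 held more tags and were more clustered than those on H3K27ac, but stood out less from their surroundings. The median signal was 12.8 normalised tags at H3K27me3 peaks, 9.75 at H3K27ac peaks and 8.25 at peaks with neither mark. The median fold over local background was 7.04 at H3K27me3 peaks and 10.06 at H3K27ac peaks. A deposited score over 27 was reached by 18.3% of H3K27me3 peaks and by 0.721% of H3K27ac peaks. Another EZH2 peak lay within 10 kb of 60.7% of the H3K27me3 peaks, 35.3% of the H3K27ac peaks and 34.5% of those with neither mark. The small group with both marks had a median of 32.3 tags, and 54.1% of it lay on unplaced contigs or within 2 Mb of a chromosome's longest stretch without any listed region.

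The knockdown list held fewer EZH2 peaks in each large class, and over all listed peaks the shortfall was greater outside H3K27me3. By the marks of control cells, H3K27me3 peaks numbered 9613 in control and 5219 in shEZH2, 45.7% fewer. H3K27ac peaks numbered 7348 and 2263, 69.2% fewer, and peaks with neither mark 5517 and 1448, 73.8% fewer. Peaks with both marks numbered 582 and 563. As peaks near the calling threshold can be lost through a small change in signal, strong peaks were also counted in each list by itself, away from contigs and the longest gaps. Strong H3K27ac peaks, with at least 15 normalised tags, numbered 792 in control and 58 in shEZH2, a ratio of 0.0732 (exact interval 0.0551 to 0.0957). Strong H3K27me3 peaks numbered 3666 and 1196, a ratio of 0.326 (0.305 to 0.348). Strong peaks with neither mark numbered 276 and 109, a ratio of 0.395 (0.313 to 0.495). On contigs and around the longest gaps, strong peaks numbered 605 and 538, a ratio of 0.889 (0.790 to 1.00). With the same minimum per kb of peak window, which allows for the narrower shEZH2 windows, these ratios were 0.224 (0.190 to 0.264), 0.525 (0.497 to 0.555), 0.678 (0.560 to 0.819) and 1.04 (0.931 to 1.17). The values and the order of the classes depended on the minimum. With at least 10 normalised tags, H3K27ac peaks numbered 3212 and 514 (interval of the ratio 0.146 to 0.176), and the ratio per kb was 0.420 (0.394 to 0.448). With at least 25 normalised tags, H3K27ac peaks numbered 44 and 16, a ratio of 0.364 (0.192 to 0.657), and H3K27me3 peaks 1667 and 245, a ratio of 0.147 (0.128 to 0.168). A ratio of numbers also depends on how many peaks lie just above the minimum. The shift in signal at equal rank, at 15 normalised tags, was -0.68 on the log2 scale (bootstrap interval -0.77 to -0.58) for H3K27ac peaks and -0.14 (-0.26 to 0) on contigs and around gaps, and for H3K27me3 peaks its interval was -1.07 to -0.97. Per kb the shifts were -0.38 for H3K27ac peaks, 0.07 on contigs and around gaps and -0.64 for H3K27me3 peaks.

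**Figure D2:**
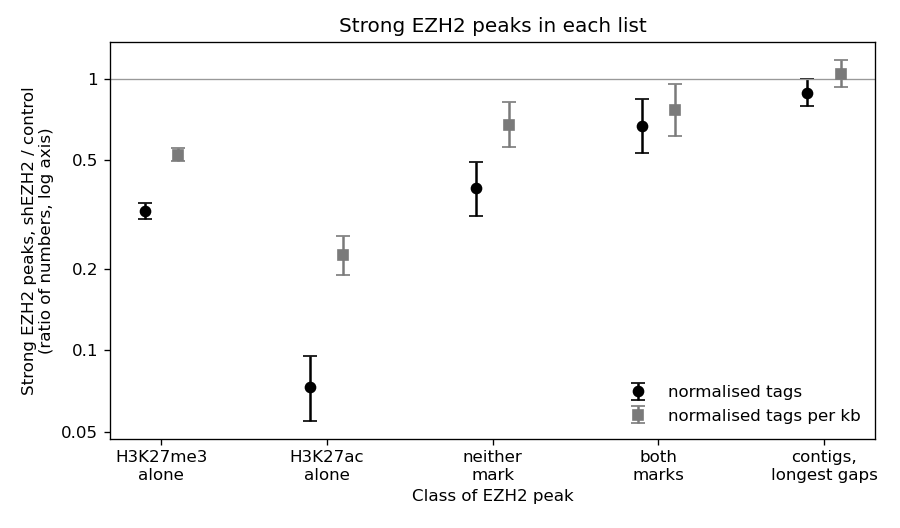
Ratio of the number of strong EZH2 peaks in shEZH2 to that in control (log axis) by class, with peaks chosen by normalised tags (circles) or by normalised tags per kb (squares) and bars giving 95% exact intervals for counting error. At this minimum of 15 normalised tags the H3K27ac class was lowest on both scales, at 0.0732 and 0.224, and the contigs and gap surroundings were nearest to 1, at 0.889 and 1.04.

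Position by position, 5330 of the 23060 control EZH2 peaks (23.1%, 22.6 to 23.7) overlapped a shEZH2 peak, against 0.149% at random placement. With both lists limited to the 9493 peaks of highest score, the share was 45.4%. In the other direction 5331 of 9493 shEZH2 peaks (56.2%, 55.2 to 57.2) overlapped a control peak and 4162 did not. Control peaks with both marks were overlapped most often, at 72.9% (69.0 to 76.4), followed by H3K27me3 peaks at 31.1% (30.2 to 32.1), H3K27ac peaks at 18.6% (17.7 to 19.5) and peaks with neither mark at 9.90% (9.12 to 10.7).

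**Figure D3:**
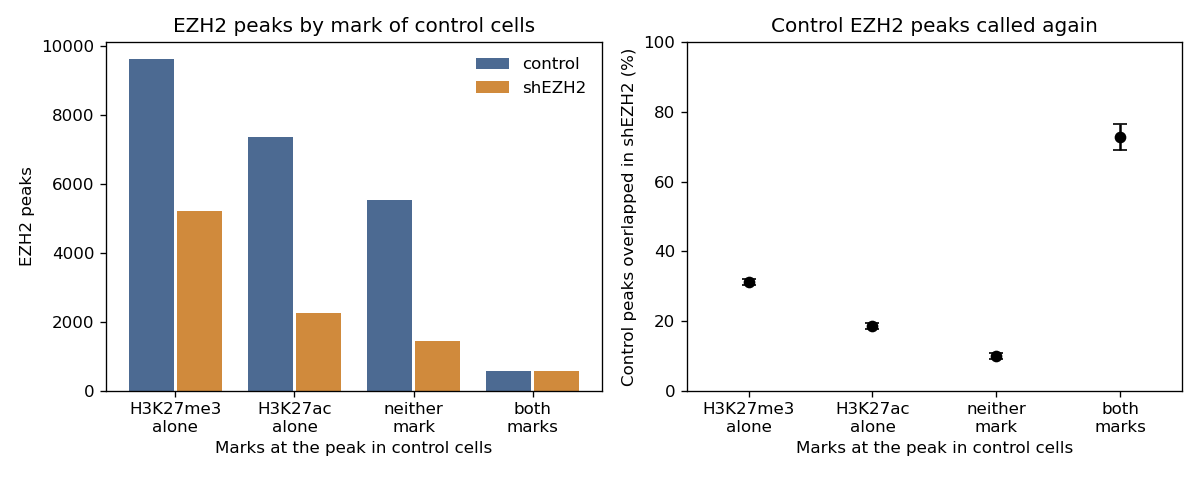
EZH2 peaks by the marks of control cells: left, peaks in each list (blue, control; orange, shEZH2); right, percent of control peaks overlapped by a shEZH2 peak, with 95% exact binomial intervals. H3K27me3 peaks were overlapped in 31.1% of cases, H3K27ac peaks in 18.6% and peaks with both marks in 72.9%.

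The share of control EZH2 peaks called again was lower without H3K27me3 (14.9%) than with it (33.5%), a difference of -18.6 percentage points (-19.7 to -17.5). For H3K27ac peaks minus H3K27me3 peaks the difference was -12.5 points (-13.8 to -11.2). Both differences changed sign when peaks of equal score were compared, to 3.71 points (SE 0.502) and 5.26 points (SE 0.586). Peaks of equal score were not matched on their fold over local background, on which a call also depended. Among peaks of score 11 to 12, 14.8% of H3K27ac peaks and 8.92% of H3K27me3 peaks were called again, a difference of 5.87 points (3.76 to 7.95). In the highest quartile, whose scores ran from 17 to 408, the difference was -10.5 points (-14.5 to -6.53), and that quartile held 3921 H3K27me3 peaks and 697 H3K27ac peaks. In 9 of 9 narrower score bins the H3K27ac share was the higher value, with overlapping intervals in the bins above a score of 14.

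**Figure D4:**
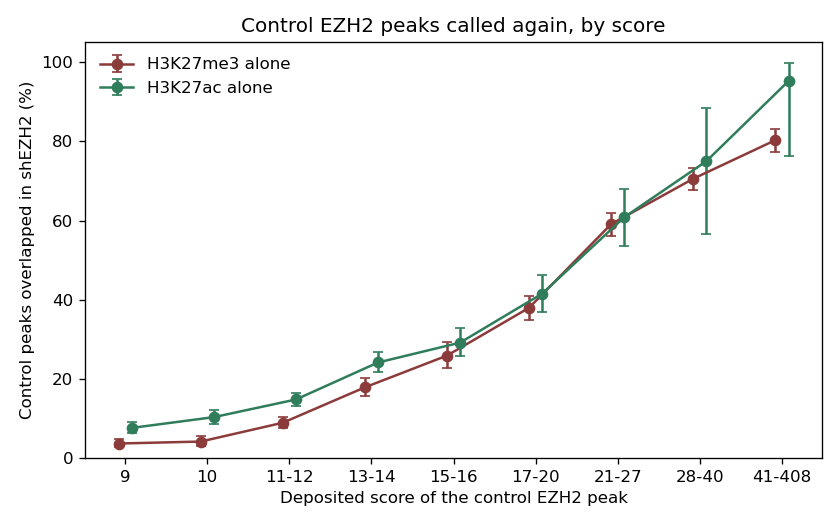
Percent of control EZH2 peaks overlapped by a shEZH2 peak (vertical axis) by deposited score of the control peak (horizontal axis), for peaks with H3K27me3 alone (red) and H3K27ac alone (green), with 95% exact binomial intervals. The share was higher at higher scores in both classes, with 3.67% and 80.3% in the lowest and highest bins for H3K27me3 peaks and 7.62% and 95.2% for the H3K27ac peaks, of which 21 were in the highest bin.

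At the 5330 EZH2 peaks called in both lists, the signal per kb was lower in shEZH2, with a median log2 ratio of -0.39 (-0.41 to -0.38) that became 0.67 when the libraries were scaled to the tags in listed peaks. Away from contigs and gaps the median was -0.66 (-0.68 to -0.63) at 2785 H3K27me3 peaks and -0.11 (-0.14 to -0.09) at 1296 H3K27ac peaks. At 650 peaks on contigs and around gaps it was 0.18 (0.12 to 0.24). Without division by the window width these medians were -0.93, -0.39 and -0.10. Only peaks that passed the shEZH2 threshold of 45.6 normalised tags per kb entered, so weaker control peaks could show only small falls. As H3K27ac peaks were weaker than H3K27me3 peaks, these medians do not show which class lost more EZH2. The value for H3K27ac peaks depended on how strong pairs were chosen. It was -0.74 (n = 135) for pairs with a control score over 20, 0.24 (-0.15 to 0.64, n = 28; -0.01 without division by width) for pairs with a shEZH2 score over 20, and -0.41 (n = 110) for pairs with a mean of over 15 tags. For H3K27me3 peaks the same choices gave -0.82, -0.73 and -0.81.

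Named regions are given by their hg19 coordinates. The 10 control EZH2 peaks of highest score with H3K27me3 all lay on contigs or near the longest gaps, led by chromosome 1 from 121485111 to 121485293 with 5118.8 normalised tags. Of the 10 highest without H3K27me3, 5 lay in such sequence. No repeat annotation was used, so the others may also lie in repeated sequence. Among them, the highest scores were on chromosome 1, from 566498 to 566680 and from 567469 to 567651. They were 4.23-fold and 4.71-fold above their local background, close to the 4-fold that a call required. The H3K27ac peak on chromosome 22 from 18879930 to 18880112 held 231 tags and was 54.35-fold above its local background. The one on chromosome 16 from 14580833 to 14581015 held 219.8 tags and was 302.27-fold above background. Both were called again in shEZH2. Their scores, 91 and 79, were low for so many tags. The peak on chromosome 1 from 566498 held 165.8 tags at a score of 153. With no input library and the clonal fold not used, it was not tested whether these tags came from EZH2 binding. All 10 of the highest-scoring peaks listed in shEZH2 alone lay on contigs or near the longest gaps. Of the 10 control EZH2 peaks of highest score not called again, with scores of 128 to 333, 5 did. One of the others, on chromosome 1 from 569346 to 569528 with neither mark, held 165.8 tags in control and was 4.29-fold above its local background. Apart from the highest-scoring, at 10.03-fold, the control peaks not called again were 4.01-fold to 5.0-fold above background. Those listed in shEZH2 alone were 4.09-fold to 5.15-fold above it. As a call needed at least 4-fold, the local filter may have decided most of these calls, which was not tested. Among H3K27me3 peaks away from gaps, the one on chromosome 7 from 157944061 to 157944243 held 465.1 tags, 59.18-fold above background, and was also called again. Its score, 174, was likewise low for its tags. The densest windows of 100 kb with H3K27me3 and EZH2 were on chromosome 5, from 140.5 to 140.6 Mb and from 140.2 to 140.3 Mb, with 16 EZH2 peaks each, of which 7 and 9 were called again. The shEZH2 list held 16 and 12 EZH2 peaks in these windows, so fewer overlapping peaks did not always mean fewer peaks. On chromosome 18, the window from 74.1 to 74.2 Mb held 15 EZH2 peaks, of which 3 were called again, and the shEZH2 list held 3 there. Over the 30 windows with 10 or more such peaks, 104 of 358 (29.1%, 24.4 to 34.1) were called again.

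H3K27ac was called in shEZH2 at nearly every site listed in control. Of 58134 control regions, 56382 (97.0%, 96.8 to 97.1) overlapped a shEZH2 region, against 7.01% at random placement and 17.6% after moves of 10 to 100 kb. The 1752 others were mostly weak: 9.29% of regions in the lowest quartile of tags were not called in shEZH2, against 2 of 14483 in the highest. H3K27ac regions holding an EZH2 peak were missing in 0.685% of cases and those without one in 3.34%, but within the lowest quartile the shares were 9.31% (6.23 to 13.3) and 9.28% (8.81 to 9.77). EZH2 peaks on H3K27ac lay in a shEZH2 H3K27ac region in 99.6% of cases. The wider shEZH2 regions made an overlap easier, and between the upper 50% of each list by score the share was 62.9%. The density needed for a call was also 3.63-fold higher in control. A region could thus lose H3K27ac and still be called, so these shares do not show that the mark was unchanged.

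Among named H3K27ac regions, chromosome 1 from 214776593 to 214777158 held 41.9 tags in control and was not called in shEZH2. Chromosome 8 from 16883930 to 16885684 held 130.8 tags in shEZH2 and chromosome 19 from 37807709 to 37810081 held 168.2, with no control region at either. Across 34954 regions called in both lists the median log2 ratio of H3K27ac per kb was -0.999, but it was 0.53 for tags per region. In 171 pairs in which the wider region was at most 25% wider it was -0.48 (-0.59 to -0.41). Within these pairs it was -0.28 (-0.37 to -0.23) at 49 regions with an EZH2 peak outside H3K27me3 and -0.64 (-0.73 to -0.51) at 116 regions without EZH2. At the former, median tags were 333.8 in control and 339.1 in shEZH2, and median widths 2608 and 3253 bp. The lower value per kb there thus came with wider regions and not with fewer tags. At the latter, median tags were 208.7 and 165.5 and median widths 2307.5 and 2737 bp. Of pairs of like width with at least 50 tags away from contigs and gaps, the lowest ratio, -2.15, was on chromosome 4 from 122744152 to 122745496, where control held 92.9 tags. On chromosome 2 from 10261757 to 10263842 the ratio was -2.05, with 141.1 and 29.3 tags. The highest, 0.14, was on chromosome 15 from 72038854 to 72041869, with 185.2 and 224.6 tags. Over all shared regions with at least 50 tags, whatever their widths, ratios ran from -3.19 on chromosome 16 from 46654731 to 46655731 to 0.87 on chromosome 7 from 100478946 to 100489453.

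H3K27me3 was likewise called in shEZH2 at most of its control sites. Of 86120 control regions, 81010 (94.1%, 93.9 to 94.2) overlapped a shEZH2 region, against 10.8% at random placement and 40.4% after moves of 10 to 100 kb. Between the upper 50% of each list by score the share was 68.6%. Of the control EZH2 peaks on H3K27me3 alone, 99.1% lay in a shEZH2 H3K27me3 region and 88 did not. The shEZH2 regions were wider, and the density needed for a call was 2.73-fold higher in control. These shares therefore do not show that H3K27me3 was unchanged. The H3K27me3 region on chromosome 3 from 196625501 to 196625903 held 791.5 tags in control and was not called in shEZH2. It was 403 bp wide and had a score of only 27. The control EZH2 peak inside it, from 196625637 to 196625819, held 853.6 tags at a score of 140, 136.62-fold above background, and was called again in shEZH2. Both scores were low for so many tags. Without an input library it was not tested whether these tags came from H3K27me3 and EZH2. The region on chromosome 22 from 18879638 to 18880638, with 51.1 tags, was listed in shEZH2 alone, and it spans the H3K27ac-marked EZH2 peak named above. Across 36496 regions called in both lists the median log2 ratio per kb was -1.06, while it was 1.63 for tags per region. In the 24 pairs of like width it was -0.24 (-0.45 to -0.08). These pairs still differed in width, with medians of 5963.5 bp in control and 6883.5 bp in shEZH2. Their median tags were 394.4 and 435.95, so tags per region were not lower in shEZH2. On chromosome 17 from 41399765 to 41401433, in such a pair, H3K27me3 was 50.5 tags in control and 27.8 in shEZH2, a log2 ratio of -0.95. Of like-width H3K27me3 pairs with at least 50 tags away from contigs and gaps, the highest ratio, 0.17, was on chromosome 4 from 9324590 to 9371319. Over all shared regions with at least 50 tags, ratios ran from -2.51 on chromosome 22 from 18717527 to 18718527 to 1.97 on chromosome 10 from 42355045 to 42401450, next to that chromosome's longest gap.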

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

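Comparisons within each score value, of H3K27ac alone with H3K27me3 alone, without repeat-rich sequence and in pairs of like width were chosen after the results were seen. Of 62 alternatives over 17 results, 11 stayed within the counting interval or within 1.5 times of the peak number, 44 moved and 7 changed sign. The upper 50% by score holds, by construction, 11530 and 4746 EZH2 peaks, 29067 and 29616 H3K27ac regions and 43060 and 49625 H3K27me3 regions (control, shEZH2). Planned promoter, gene-list and sequence alternatives were not run. No paired analysis was possible because each group held 1 library.

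With 50% of the peak covered, a distance of 1 kb and the upper 50% by score, in that order, the share of EZH2 peaks called again was 16.3%, 33.9% and 26.3%, the share in H3K27me3 40.9%, 51.9% and 46.5%, and the share in H3K27ac 32.4%, 37.7% and 23.4%. H3K27ac regions called again came to 96.7%, 97.8% and 62.9%, and H3K27me3 regions to 93.6%, 96.2% and 68.6%. The difference in H3K27ac overlap was 46.5, 59.0 and 34.0 points. For peaks called again, H3K27ac minus H3K27me3 was -9.61, -16.0 and -23.2 points, and without minus with H3K27me3 was -13.5 and -23.9 points under the 2 overlap choices. The cause was not tested.

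Lists of equal length gave 45.4% of EZH2 peaks and 92.6% of H3K27me3 regions called again. Without repeat-rich sequence, 21.8% of EZH2 peaks were called again, 43.2% lay in H3K27me3 and the H3K27ac difference was 55.3 points. With H3K27me3 of both groups, 56.8% of EZH2 peaks carried it. Within score quartiles the H3K27ac difference was 59.2 points, and the differences in peaks called again changed sign to 0.194 and 1.31 points, and within each score value to 3.71 and 5.26. The classes differ in score, and also in fold over local background, on which peaks were not matched.

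The log2 ratio of H3K27ac was 0.53 for tags per region, -0.96 with at least 50 tags, -1.35 scaled to tags in regions and -0.48 in pairs of like width. For H3K27me3 these were 1.63, -1.04, -2.42 and -0.24. The sign depended on dividing by width, which the calls set. Pairs of like width still differed, with median widths of 2436 and 2887 bp for H3K27ac and 5963.5 and 6883.5 bp for H3K27me3 (control, shEZH2). The EZH2 ratio was -0.67 for tags per peak, -0.69 with at least 50 tags and 0.67 scaled to tags in peaks, a scaling that removes the lower EZH2 share of tags itself.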

Other observations

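The tests in this part on called regions, peak strength and repeat-rich sequence were chosen after the results were seen, whereas those on open chromatin and regional signal were written down before their values were computed, the count of strong peaks only after the paired test had been seen to depend on the choice of pairs. The minimums of 10 and 25 normalised tags and the shift at equal rank were chosen after those counts were seen. EZH2 peaks were sparse on chromosome X, with 1.44 per Mb against 7.78 per Mb on the autosomes in control, and 0.457 against 3.15 in shEZH2. H3K27me3 regions numbered 2.70 per Mb on X and 29.4 on the autosomes in control, while H3K27ac regions numbered 8.98 and 19.3 per Mb. The number of copies of X was not taken into account, and the cause of these differences was not tested. EZH2 peaks with neither mark in control lay in a shEZH2 H3K27me3 region in 48.6% of cases, in the list called at the lower density.

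H3K27me3 and H3K27ac regions covered more of the genome in shEZH2 than in control. The lower density threshold and wider window of the shEZH2 calls may account for this. Of the 1586 shEZH2 H3K27me3 regions as dense as the control threshold (1.60% of the list), 99.8% overlapped a control region, and of the 73660 below 50% of that threshold (74.2%), 21.7% did. For H3K27ac the overlaps were 99.9% of 13156 regions (22.2% of the list) and 29.3% of 32252. A gain of either mark at low density stays open, since the control lists hold no regions below their own threshold.

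EZH2 peaks with H3K27me3 were called again in shEZH2 more often than those with H3K27ac. Sequence on contigs and around the longest gaps is argued against as the whole cause, since the difference was -12.6 points without it. Repeats elsewhere were not removed, so their part was not tested. The higher scores of H3K27me3 peaks may be the cause, although their median fold over local background was the lower one (7.04 against 10.06), as the difference at equal score was 5.26 points in favour of H3K27ac peaks (4.11 to 6.40). A call also needed at least 4-fold over local background, and peaks of equal score were not matched on that fold. The sign at equal score therefore does not show which class lost more EZH2. Whether EZH2 was lost to a different extent at either class of equal starting strength stays open with 1 library per group.

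EZH2 peaks lay in H3K27ac regions without H3K27me3. Regional signal is argued against, since peaks moved by 10 to 100 kb reached 9.56% of the observed share. Pull-down of open chromatin that does not depend on EZH2 may also place peaks there, and it cannot be told apart from EZH2 binding, because the tests below compare 1 library with 1 other of different fragment length (182 and 150 bp), their intervals leave out the spread between libraries, and the bounds set for them had ignored this. The strongest H3K27ac peaks were shifted relative to repeat-rich peaks by -0.54 (-0.73 to -0.40) on the log2 scale, or -0.45 per kb (-0.59 to -0.38), and per kb their number in shEZH2 over control was 0.420 at 10 normalised tags, 0.224 at 15 and, with 22 over 44 peaks, between 0.285 and 0.852 at 25. In pairs, H3K27ac minus repeat-rich log2 ratios were -0.92 chosen by control score, -0.10 by shEZH2 score and -0.67 by mean tags, and a less efficient EZH2 immunoprecipitation in shEZH2, which could lower every class, was not tested.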
